A study of Mus musculus with 6 samples.

How the data were processed

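Total RNA from the hippocampus of 3 wildtype and 3 Nes-cKO male mice was extracted with Trizol, and strand-specific libraries of polyadenylated RNA were read as paired 50 bp reads, per the labels' protocols. The submitters' processing notes name CASAVA, Cufflinks, Cuffdiff and the mouse build mm9, without versions. The aligner was not given in the sources used here.

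The gene table held, per the file headers, 1 FPKM value per gene and genotype, together with a test score, p-values and q-values deposited by the authors. Of 23235 genes, 14964 had a test, 8270 had too little signal for one and 1 failed. The deposited q-values equalled a Benjamini-Hochberg adjustment over the tested genes to within 5.21e-07, and the smallest deposited p-value, 5e-05, was shared by 491 genes, so the deposited table does not rank these. The deposited fold change column was not used here because 460 of its cells held a spreadsheet error, and 25 gene symbols had become dates. The log2 ratio of Nes-cKO over wildtype was computed from the authors' FPKM with no pseudocount. For 2 changed genes, listed at 0 in wildtype, no ratio was given.

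The 4 splicing tables held, per the file headers, an inclusion ratio (a fraction from 0 to 1) per event and genotype, the change, p-values deposited by the authors and whole junction read counts per genotype. They list events with a change above 10 percentage points, so the counts are not rates over all exons. The deposited p-values equalled a one-sided normal tail of the change, with 1 mean and SD fitted per event type (SD 0.0254 for cassette exons), so read depth and variation between mice do not enter them. From the authors' junction counts, the inclusion reads were taken as the rounded mean of the 2 inclusion junctions and set against the skipping reads. Fisher's exact test (two-sided) compared the genotypes per event, with Benjamini-Hochberg adjustment within each event type. Cassette exons had between 13 and 1411 such reads in wildtype and between 18 and 1291 in Nes-cKO, and the number of reads per library is unknown. Wilson intervals were computed at the 95% level from these reads and cover counting error only.

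Coordinates are those of the authors' tables in mm9, written from base 1. Symbols of 306 of the 320 splicing events matched the gene table directly and 316 after synonyms from the RefSeq gene table of the GRCm38.p6 assembly, used for names only.

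The design fixed before the data were examined provided for values per mouse and for group values. Group values were found, so the q of 0.05 in the authors' deposited table was the threshold, and no test of expression was run here. For 25 gene lists fixed in advance, members with an FPKM of at least 1 in either genotype were counted by direction, also with the deposited p-values adjusted over the list alone. The median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, which describes these libraries and gives no p-value. Lists overlap, so a gene such as Calb2 counts in several. Directions of cassette exons were tested with an exact binomial test, and the overlap of expression and splicing with Fisher's exact test. The genes named are Rbfox1, Rbfox2, Rbfox3 and Vamp1, the 12 steepest rises and 12 steepest falls past the threshold with an FPKM of at least 1 in either genotype, up to 4 changed members per list by size of change (or the 2 most highly expressed), the 8 cassette exons with the greatest change each way, 2 each way for the other event types, and up to 10 events in known Rbfox target genes. Some genes that this rule selects are not reported here. Other names were chosen after their values were seen.

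The list and junction-read steps were tested on simulated data. With 12670 genes, the central 95% range was left by 5% of simulated lists of 20 genes with no change, by 93% with a shift of 0.3 in log2 and by 100% with a shift of 0.6. With 249 cassette exons at the real depth, the junction-read test passed 0% of exons with no simulated change, 24.1% with a change of 0.1 in inclusion and 90.4% with a change of 0.3. Simulated genes varied independently and simulated reads held counting error only. Shared variation of list members and variation between mice were therefore not covered by these simulations. Other thresholds, filters and random lists were tried as alternatives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, and figures were drawn with matplotlib 3.10.9.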

Results

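Hippocampal RNA from 6 adult male mice, aged 60 to 70 days, was sequenced as paired 50 bp reads. Of the 6 mice, 3 were wildtype, carrying Rbfox1 alleles flanked by loxP sites but no Cre recombinase. The other 3 carried the same alleles together with a Nestin-driven Cre (Nes-cKO), which deletes the gene in neural progenitors and so in the neurons and glia that descend from them. Rbfox1 encodes an RNA-binding protein that regulates alternative splicing and, in the cytoplasm, messenger RNA level. The comparison asked which transcripts and which alternative exons differed between the genotypes. Expression was given as the authors' FPKM, a length- and depth-scaled level, with 1 value per gene and genotype. Exon inclusion was likewise given as 1 value per event and genotype, so no spread between mice was analysed here and no value below has a replicate error. Reads per library are unknown from these values. Splicing events had a median of 83 junction reads in each genotype for cassette exons.

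Rbfox1 transcripts were lower in Nes-cKO hippocampus, and the transcript of the vesicle fusion protein Vamp1 was lower as well. Rbfox1 (mm9 chromosome 16, 5884886 to 7412573) stood at 67.5 FPKM in wildtype and 23.0 FPKM in Nes-cKO, 34.0% of the wildtype level. This is a value for the whole gene, so exons outside the deleted part add to it. Vamp1 (chromosome 6, 125165599 to 125172324) fell from 41.9 to 22.0 FPKM, a ratio of 1.91. The q-value of both genes in the authors' deposited table was 0.00152, the smallest that table holds. Vamp1 was named in advance because the study behind these samples is remembered to have followed it, so it is not independent evidence. The paralog Rbfox2 stood at 35.4 FPKM in wildtype and 44.1 FPKM in Nes-cKO, with q = 0.0803 in the authors' deposited table. The neuronal paralog Rbfox3 stood at 72.8 and 83.4 FPKM, with q = 0.498 in the authors' deposited table.

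Across the hippocampus, more transcripts rose than fell. In the authors' deposited table, 1035 of 14964 tested genes passed a q of 0.05, of which 692 were higher and 343 lower in Nes-cKO. Most changes were small: the median absolute log2 ratio of the changed genes was 0.63, and 187 genes rose and 49 fell at least 2-fold. The median log2 ratio of tested genes with an FPKM of at least 1 was 0.03. Without the cerebellar marker genes described below, which were chosen after the data were seen, 673 genes were higher and 343 lower. This removed the listed markers only, so other transcripts that carry-over of cerebellar tissue could raise are still counted. The count rests on the authors' test of 3 against 3 mice, and with no values per mouse it was not tested again here.

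Among changed genes with an FPKM of at least 1 in either genotype, the 12 steepest rises were in transcripts that stood at or below 2.16 FPKM in wildtype. Arhgap36 rose from 0.221 to 4.86 FPKM. The transcription factor genes Fosb and Atf3 rose 7.93-fold and 7.86-fold, to 14.5 and 2.88 FPKM. The ligand genes Bmp3, Inhba (an activin subunit) and Gal (the neuropeptide galanin) reached 3.59, 5.87 and 4.40 FPKM, rises of 7.46-fold, 5.94-fold and 5.41-fold. Ecel1, Prlr (the prolactin receptor) and Ly6g6e rose 6.91-fold, 6.45-fold and 5.12-fold. Dgat2l6, Tmem40 and the meiotic cohesin gene Rec8 completed the 12 steepest rises, at 1.26, 1.10 and 1.01 FPKM in Nes-cKO. Among the falls, Zcchc5 dropped from 1.60 to 0.144 FPKM and Gdpd3 from 2.12 to 0.268 FPKM. Hipk4, a kinase gene, fell from 8.51 to 1.60 FPKM. Tdo2, which encodes a tryptophan dioxygenase, fell from 4.37 to 0.952 FPKM, and Ntf3, which encodes neurotrophin 3, from 5.96 to 1.64 FPKM. The opioid precursor gene Pdyn fell from 4.70 to 1.49 FPKM. Ogn, Tuba1c, Stc1, Sec1 and Gm606 were the remaining genes among the 12 steepest falls besides Rbfox1, with wildtype levels between 1.11 and 2.63 FPKM. All of these genes passed the q of 0.05 in the authors' deposited table. The sizes of change at low FPKM depend on the scale: with a pseudocount of 1, the log2 ratio of Atf3 went from 2.97 to 1.51, of Prlr from 2.69 to 1.09, of Dgat2l6 from 2.86 to 0.95 and of Zcchc5 from -3.48 to -1.18, and Nptx2 at 1.97 and Rprm at 1.50 then lay above several of the 12 rises named.

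Genes that neuronal activity induces were higher as a group. Of 34 measured members, 18 rose, 2 fell and 14 did not pass, and 20 rose and 3 fell when adjusted over the list alone. Nptx2, a synaptic pentraxin, rose from 9.48 to 40.1 FPKM. The neuropeptide gene Npy rose from 77.3 to 193 FPKM, the opioid precursor gene Penk from 15.2 to 36.4 FPKM and the neurotrophin gene Bdnf from 8.84 to 21.2 FPKM. Fos rose from 5.41 to 10.3 FPKM and Egr3 from 19.9 to 55.8 FPKM. Pdyn and Btg2 were the members that fell. The immediate early genes Arc (42.9 and 34.2 FPKM), Npas4 (3.73 and 2.98 FPKM) and Nr4a1 (21.5 and 18.5 FPKM) did not pass. Bdnf, Fos, Egr3, Btg2, Arc, Npas4 and Nr4a1 were singled out after their values were seen. The median log2 ratio of the list was 0.53, at percentile 100 among 10000 random lists of the same size and expression. Of 20 stress and glucocorticoid response genes, Atf3 and Cdkn1a rose, Sult1a1 and Tsc22d3 fell and 16 did not pass, with 4 higher and 2 lower when adjusted over the list alone. The median of that list was 0.01, at percentile 25.2.

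Markers of the myelinating cells were lower, while those of other glia showed no shared shift. Of 18 oligodendrocyte markers, 14 fell, none rose and 4 did not pass, and 16 fell when adjusted over the list alone. The myelin genes Mbp, Mobp and Mal fell from 1006 to 679, from 58.9 to 36.1 and from 74.0 to 45.1 FPKM, and the transferrin gene Trf from 86.6 to 56.8 FPKM. The list had a median log2 ratio of -0.50, at percentile 0 among the random lists. Of 11 oligodendrocyte precursor markers, Bcas1, which maturing oligodendrocytes also express, fell from 44.1 to 29.7 FPKM and 10 did not pass, the same count when adjusted over the list alone, at percentile 3.81. Among 18 astrocyte markers the intermediate filament gene Gfap rose 2.02-fold, from 106 to 214 FPKM, and the water channel gene Aqp4 rose 1.50-fold. Glul, the glutamine synthetase gene, fell from 461 to 313 FPKM, and 15 astrocyte markers did not pass, with the same counts when adjusted over the list alone and a median at percentile 25.1. None of 18 microglia markers passed in the authors' deposited table or when adjusted over the list alone, with Ctss at 42.8 and 36.2 FPKM and a median at percentile 4.08. Of 18 endothelial and mural cell markers, Kdr rose 1.54-fold and 17 did not pass, again also when adjusted over the list alone. The median of that list was -0.02 and its mean 0.00406, at percentile 14.7.

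**Figure D1:**
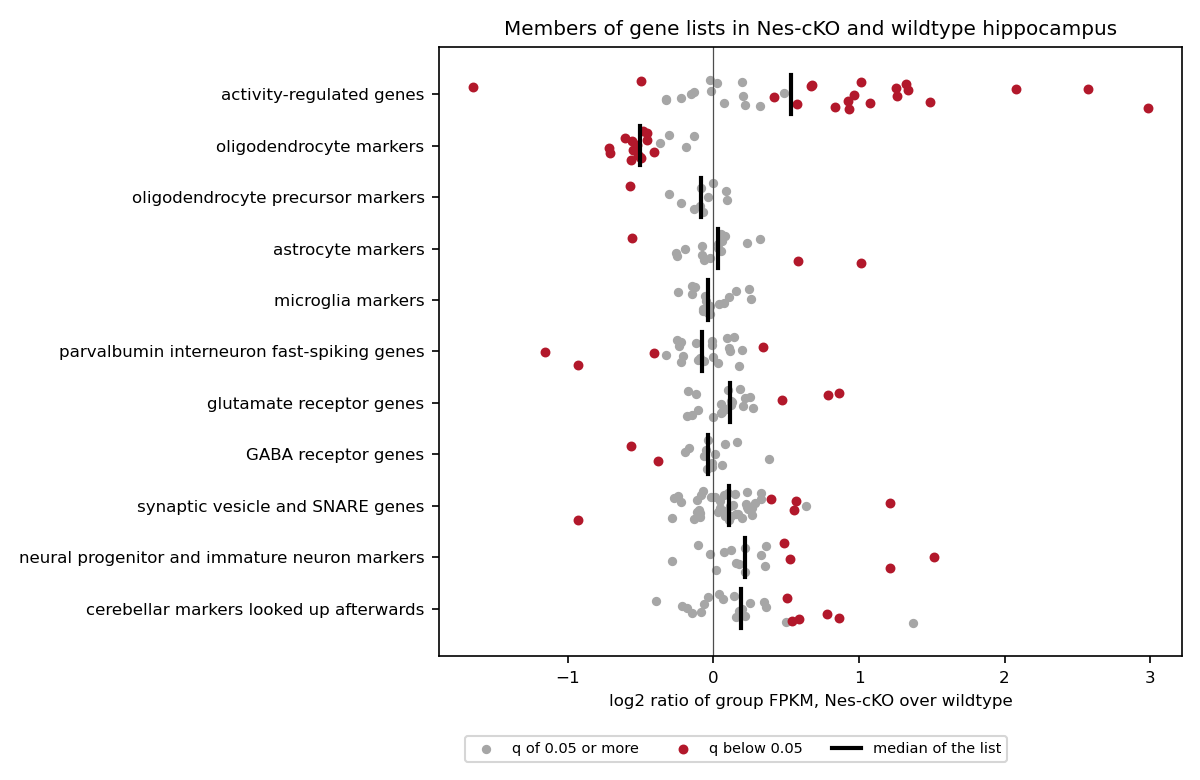
Log2 ratio of the authors' FPKM in Nes-cKO over wildtype (horizontal axis) for the members of 11 gene lists (rows), with an FPKM of at least 1 in either genotype; each point is a gene, red where the deposited q was below 0.05, and the black bar is the median of the list. The activity-regulated genes spread to the right of 0 with a median of 0.53, and all 18 oligodendrocyte markers lie left of 0 with a median of -0.50.

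Some interneuron genes rose and others fell. Among 27 interneuron markers Npy, Calb2 (calretinin) and Reln rose, Cort (cortistatin) fell from 4.21 to 2.00 FPKM and 23 did not pass, with the same counts when adjusted over the list alone. The median of this list was -0.02 and its mean 0.03, at percentile 10.4. Of 24 genes of parvalbumin interneurons and fast spiking, the sodium channel genes Scn4b and Scn1a fell with Vamp1, 1 rose and 20 did not pass, and 4 fell and 1 rose when adjusted over the list alone. Scn4b went from 4.55 to 2.04 FPKM. The median of that list was -0.08, at percentile 0.21, and Pvalb itself stood at 29.3 and 33.1 FPKM without passing. Of 24 pyramidal and granule neuron markers, 3 rose, 3 fell and 18 did not pass, with Neurod2 up from 42.1 to 74.1 FPKM, Grik4 up 1.39-fold, and Dock10 and Cpne4 at 71.4% and 72.6% of wildtype. Adjusted over the list alone, 6 rose and 4 fell, and the median was -0.00156 and the mean 0.02, at percentile 8.82. Of 17 markers of progenitors and immature neurons, Igfbpl1, Sox11, Calb2 and Fabp7 rose and 13 did not pass, with 5 higher when adjusted over the list alone. Sox11 rose from 1.93 to 4.48 FPKM, and the median of 0.22 lay at percentile 99.97.

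Channel and synapse genes moved in both directions. Of 41 voltage-gated channel genes, 5 rose, 5 fell and 31 did not pass, and the same numbers held when adjusted over the list alone. The T-type calcium channel genes Cacna1g and Cacna1h rose from 8.54 to 22.7 and from 19.3 to 30.3 FPKM, and the auxiliary subunit gene Cacna2d2 rose 2.20-fold. The median of this list was -0.04 and its mean 0.03, at percentile 0.105. Among 22 glutamate receptor genes Grm2 rose from 16.9 to 29.1 FPKM with Grm4 and Grik4, and 19 did not pass, also when adjusted over the list alone, with a median at percentile 98.8. Of 15 GABA receptor genes, Gabrd fell from 12.6 to 8.50 FPKM, Gabra5 fell from 66.3 to 51.0 FPKM and 13 did not pass, with 1 higher and 2 lower when adjusted over the list alone and a median at percentile 3.27. Of 44 synaptic vesicle and SNARE genes, 4 rose, including Sv2c, Cplx3 and Syt5, Vamp1 fell and 39 did not pass, with 5 higher and 1 lower when adjusted over the list alone. The median of 0.10 lay at percentile 99.2. Of 35 synaptic adhesion genes, Nrxn2 rose, Cntnap1 fell and 33 did not pass, also when adjusted over the list alone, at percentile 84.3. Of 33 RNA-binding splicing regulators, Srrm4 rose 1.37-fold, Rbm24 fell from 4.91 to 2.60 FPKM with Rbfox1, and 30 did not pass. Adjusted over the list alone, 3 of them rose and 3 fell, and the median was 0.08 and the mean -0.01, at percentile 89.7. Of 75 genes known before as Rbfox splicing targets, 8 rose, among them Camk2d, Lrp8 and Ptprf, Rbfox1 fell and 66 did not pass, with 10 higher and 1 lower when adjusted over the list alone, at percentile 11.4.

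Transcripts of neighbouring tissues differed too, in the same libraries as each of the groups above. Of 13 thalamus and habenula markers, Lhx9, Prkcd and Ntng1 fell, Zic1 and Calb2 rose and 8 did not pass, also when adjusted over the list alone, and the median of -0.30 lay at percentile 0. Ntng1 was singled out after its value was seen. Of 10 choroid plexus and ependymal markers, Ttr fell from 12.4 to 7.51 FPKM with Lbp, Prlr rose and 7 did not pass, with 1 higher and 3 lower when adjusted over the list alone, at percentile 0.64. Of 14 meningeal and fibroblast markers, Col1a1 and Col1a2 rose, Ogn and Slc6a13 were among 3 that fell and 9 did not pass, with 4 higher and 3 lower when adjusted over the list alone, at percentile 13.3. Of 11 striatum markers, Drd1a and Penk rose, Scn4b fell and 8 did not pass, with 3 higher and 1 lower when adjusted over the list alone, at percentile 90.9. Of 17 neocortex layer markers, 5 rose, including Rprm (from 15.9 to 46.6 FPKM) and Ctgf, and 2 fell, 6330527O06Rik and Rasgrf2, also when adjusted over the list alone, while 10 did not pass, at percentile 94.3. Only 2 blood cell markers could be measured, which was too few for a percentile, and of these 1 rose, also when adjusted over the list alone, while the haemoglobin gene Hba-a2, at 1.57 and 0.00645 FPKM, did not pass. No mitochondrially encoded gene was in the table. Several genes typical of cerebellum were noticed among the higher ones, such as Gabra6, a GABA receptor subunit gene of cerebellar granule neurons (3.51 and 10.5 FPKM), and Cbln3 (3.98 and 11.4 FPKM). Of 24 measured cerebellar markers looked up afterwards, 5 rose, none fell and 19 did not pass, also when adjusted over the list alone.

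Cassette exons were both gained and lost in Nes-cKO hippocampus. The authors' deposited table listed 249 cassette exons under 233 gene symbols whose inclusion differed by more than 10 percentage points, 133 lower and 116 higher in Nes-cKO. The lower share was 53.4% (95% exact Clopper-Pearson interval 47.0% to 59.7%, two-sided exact binomial p = 0.311), which does not separate it from an even split. Exons of one gene are not independent. The deposited p-value was below 0.05 for every listed event, but it could be recovered from the inclusion difference alone, with a single normal spread per event type, and so takes no account of reads or mice. Junction reads were therefore tested as well, a choice made after the data were seen. With Fisher's exact test on the pooled reads and Benjamini-Hochberg adjustment, 60 of the 249 exons passed in the same direction, 37 lower and 23 higher, a test that compares the pooled libraries and not the conditions.

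The 8 greatest listed losses of inclusion ran from Prpf18 and Stx3 to Dync1i2. Each value that follows is the authors' inclusion ratio for the genotype, in percent. A 27 nt exon of the splicing factor gene Prpf18 (chromosome 2, 4569143 to 4569169) went from 81.9% to 42.3%. A 46 nt exon of the syntaxin gene Stx3 (chromosome 19, 11864538 to 11864583) went from 81.9% to 42.5%, and a 31 nt exon of Camta1 (chromosome 4, 150445535 to 150445565) from 48.4% to 12.1%. A 43 nt exon of Camkk2, a kinase gene of the calmodulin pathway that the table lists under mKIAA0787, went from 90.3% to 57.4%. The Camkk2 transcript also fell, from 24.6 to 14.6 FPKM. Exons of D16H22S680E, Camk2g and Dync1i2 (listed as Dncic2) went from 55.2% to 22.4%, from 67.3% to 35.2% and from 43.1% to 16.8%. Each of these 7 exons passed the junction-read test. A 157 nt exon of Homer1 was listed at 92.8% and 65.5%, yet its junction reads gave 97.5% (161 reads) and 96.0% (176 reads) and did not pass.

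Gains of inclusion were led by a potassium channel exon. A 57 nt exon of Kcnd3 (chromosome 3, 105469880 to 105469936) went from 44.0% to 90.9%. A 111 nt exon of Cttn, which encodes the actin-binding protein cortactin, went from 26.1% to 53.7%. Exons of Dock9 (3 nt), Acox3, Stxbp5l and Synpo went from 57.1% to 84.5%, from 74.0% to 99.9%, from 62.7% to 88.3% and from 30.7% to 53.1%, and all 6 of these exons passed the junction-read test. An exon of Cnnm3 (76.8% and 99.9%) did not pass it.

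**Figure D2:**
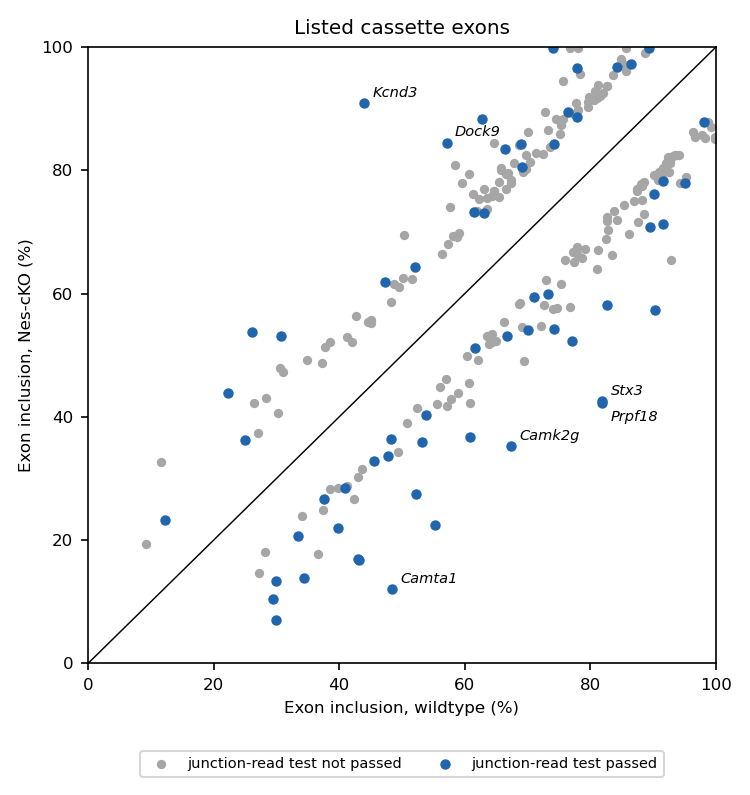
Inclusion of the 249 listed cassette exons in wildtype (horizontal axis, %) and Nes-cKO (vertical axis, %), each point an exon and the line equal inclusion; blue points passed Fisher's exact test on the pooled junction reads after adjustment. The empty band along the line is the 10 percentage point minimum of the list, and Kcnd3 (44.0% and 90.9%) and Prpf18 (81.9% and 42.3%) lie far from it.

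Known Rbfox target genes held 16 of the listed cassette exons, in 12 genes, with 11 exons lower and 5 higher, and 10 of the 16 passed the junction-read test. Of all 249 listed cassette exons, 60 passed it in the same direction, a condition not set for the 10. Stx3, Camta1, Camk2g and Kcnd3 were among these genes. Rbfox1, the deleted gene, was itself on the list of known targets. Its 53 nt exon (chromosome 16, 7392081 to 7392133) went from 53.2% to 36.0% and passed. In Ptprf, which encodes a receptor phosphatase, a 33 nt exon went from 66.4% to 83.4% and passed, while a 27 nt exon at 68.6% and 84.1% did not. Ptprf exons of 579 nt (43.0% and 30.2%) and 306 nt (27.2% and 14.7%), singled out after their values were seen, were listed as lower and did not pass.

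Fewer events were listed for alternative splice sites and retained introns. The authors' deposited table held 31 alternative 3' splice sites, 14 lower and 17 higher, and 35 alternative 5' splice sites, 21 lower and 14 higher. The junction-read test was passed by 6 events of either kind. Among the 5' events, use of a 78 nt extension in Tacc2 went from 44.5% to 20.9% and of a 15 nt extension in Bai1, an adhesion receptor gene, from 15.1% to 35.0%, and both passed. Fkbp15, at 60.9% and 77.6%, passed too, whereas the Asap1 extensions of 7 nt (49.4% and 26.0%) and 36 nt (74.9% and 59.9%) did not. Among the 3' events, Bat3 and Cux1 had the greatest listed decreases and Ppapdc1b and ORF3 the greatest listed increases, and none of these 4 passed. Of 5 retained introns, 3 were higher. The Vamp1 intron (chromosome 6, 125169656 to 125170067) went from 21.1% to 32.7% retention and passed the junction-read test, as did that of Myo9b (64.7% and 85.3%). The introns of Znf512b and Tmem208, listed as lower, did not pass.

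No excess of expression changes was detected among genes with a listed cassette exon. Among genes with an FPKM of at least 1, 17 of 228 with a listed cassette exon (7.46%) passed the q of 0.05 in the authors' deposited table, against 884 of 12457 others (7.10%). The odds ratio was 1.05 (two-sided Fisher's exact p = 0.795). The other genes include some with no alternative exon that could have been listed. Rbfox1, Camkk2, Kcnd3, Stx3, Synpo and Ptprf were among the genes in both sets.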

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

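No paired analysis was possible because the tables hold 1 value per genotype, so the replicate numbers of the mice have no columns. For the same reason leaving out a mouse, other splits of the mice, another pseudocount or normalization in a test, and a test on the logit of inclusion were not run. The search for the Rbfox motif beside cassette exons was not run because no mm9 sequence was used here. The junction-read test, the FPKM minimum of 1, the removal of cerebellar markers and the centred ratio were chosen after seeing the data. Of 1035 changed genes (692 higher, 343 lower), 674 passed an adjusted p of 0.01 (196 lower) and 595 had an FPKM of at least 5 (413 higher, 182 lower), and 228 lower genes had an absolute log2 ratio of at least 0.5. These counts shrink by construction. A change of at least 20 percentage points left 28 of 249 cassette exons, 3 of 31 alternative 3' splice sites, 4 of 35 alternative 5' splice sites and 1 of 5 retained introns. A deposited p below 0.01 left 9 alternative 3' and 16 alternative 5' splice sites. The junction-read test left 60 cassette exons, 6 and 6 alternative splice sites and 3 retained introns. In the simulation 24.1% of exons with a change of 0.1 passed that test, so depth can limit it. The simulated change was present in the reads, so the simulation does not show why a listed event failed. Junction reads moved in the listed direction for 241 of the 249 cassette exons, but for some, such as those of Homer1, by far less than listed. In the remaining 33 recalculations of the main results, the count stayed within 1.5 times or the test on the same side of its threshold. The number of lists outside the central 95% of random lists was 9, and 9 to 10 under the alternatives, the added list being the blood cell markers, too few before, whose 5 tested members had a median log2 ratio of -0.57, at percentile 0.19. None of the 336 recalculations for single lists and genes took a list into or out of the central range or changed the direction of a gene. The median log2 ratio of the stress and glucocorticoid list, close to 0, went from 0.00704 to -0.00956 over all members with a test.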

Other observations

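All tests in this part were chosen after the results were seen, and the division of the activity list was drawn up with expression values already known. The cerebellar markers were listed after some had been noticed among the higher genes, and the tested ones before their own values had been looked at.

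The Homer1 transcript rose from 16.6 to 32.4 FPKM. A second Homer1 exon of 36 nt was listed at 94.2% and 77.9% inclusion while its junction reads gave 95.7% (116 reads) and 94.7% (113 reads) and did not pass. Cassette exons lost in Nes-cKO had a length divisible by 3 in 57.9% of cases and gained ones in 52.6% (two-sided Fisher's exact p = 0.444). Exons of up to 27 nt made up 6.77% of the lost and 7.76% of the gained exons (two-sided Fisher's exact p = 0.81). A 40 nt exon of Rbfox2 went from 77.8% to 88.6% inclusion and passed the junction-read test.

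Transcripts typical of cerebellum were higher in the Nes-cKO group. After 11 such genes were noticed among the higher ones, 38 more markers were looked up, and of the 24 that could be measured 5 rose and none fell. Their median log2 ratio was 0.19, above the 95% range of matched random lists (-0.05 to 0.10), which is what carry-over of cerebellar tissue would give, and 23 of the 24 were also at an FPKM of at least 1 in wildtype. The Purkinje gene Pcp2 stood at 4.60 and 11.9 FPKM without passing. Calb1 (45.1 and 42.6 FPKM) and Itpr1 (36.4 and 32.9 FPKM), already high in wildtype, were not higher in Nes-cKO. Whether a small share of cerebellar tissue would show in them is unknown, since no cerebellar sample was analysed here. The same median argues against a general gain of transcripts at these levels, which the matched lists would share. Carry-over may thus account for part of the rise. An effect of the genotype on these genes stays open, since no value per mouse shows whether a single dissection carries the rise. Genes of the other lists that cerebellum also expresses could be raised by carry-over too, which was not tested.

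Activity-regulated genes were higher in the Nes-cKO group, with a median log2 ratio of 0.53. Acute handling or the time to dissection could raise rapid transcription factors first. Over all 34 members, the 10 with a secreted product had a median log2 ratio of 0.97 and the other 24 of 0.37, a difference of 0.60 (permutation test, p = 0.169). The division is by secretion and not by speed of induction, so it cannot tell handling apart from the genotype. An earlier division of 20 of the members into rapid and longer-lasting genes was discarded because its classes had been picked with their values in view. An effect of the genotype on neuronal activity remains an untested hypothesis.

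Oligodendrocyte markers were lower in the Nes-cKO group by a similar factor. The interquartile range of their log2 ratios was 0.14, inside the range of matched random lists (0.08 to 0.29), at percentile 29.2. Less white matter or fewer oligodendrocytes in the tissue would give such a spread, and a uniform drop in transcription would look alike. Random lists of genes spread as little, so the spread favours none of these causes. A loss of all glia alike is argued against, since the higher of the astrocyte and microglia medians was 0.0290 against an upper quartile of -0.42 for the oligodendrocyte markers. A different dissection border with the thalamus could lower the markers of that region. The median of the thalamus and habenula list was -0.30, below the range of matched random lists (-0.12 to 0.13). Lhx9, Prkcd and Ntng1 of that list fell, while Zic1 and Calb2 rose. Whether the carry-over of cerebellar tissue described above raised Zic1 and Calb2 was not tested. With 1 value per genotype, such a border cannot be told apart from other causes. A genotype effect on oligodendrocytes, which descend from Nestin-expressing progenitors, is also open and untested.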
